A study of Homo sapiens with 9 samples.

How the data were processed

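Whole-tumour total RNA of the human hepatocellular line Hep3B, grown in the livers of Nod/Scid mice for about 5 weeks, was biotin-labelled and hybridised to 9 Illumina expression arrays. Per the labels, the tumours were taken 24 hours after 1 intravenous injection of dilution buffer, empty liposomes or MRX34, a liposomal mimic of the microRNA miR-34a. The sample names put 3 arrays in each group, and both control articles are numbered together as controls. The labels do not state whether each array came from a separate animal, so the p-values measure the spread between these samples.

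The deposited table with detection p-values holds intensity values that were already quantile normalized between arrays and not background-subtracted. This was read from the values: the 9 columns held the same sorted intensities to within 2 units, from 50.3 to 47789. Per the file headers, each intensity column of that table is followed by a detection p-value, and its steps of 1 in 770 were read as the number of negative controls. The deposited series table holds intensity values that were background-subtracted and not normalized between arrays, since they reach below 0 and their array means differ. The 2 tables ordered the probes of each array alike. The scanner software and the authors' method of normalization are not given in the sources used here.

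Signals were background-corrected in R 4.3.3 with limma 3.58.1 (normexp with the negative-control level taken from the detection p-values), raised by an offset of 16, quantile normalized and put on the log2 scale. The offset shrinks the fold changes of dim probes. A probe entered the tests when its detection p was under 0.05 on at least 3 of the 9 arrays. Of 47322 probes, 3270 without a symbol, 92 spike-in controls and 54 whose symbol reads as a date were set aside. The other 43906 were named from the symbols in the deposited table. Among them 27035 had a current symbol in the RefSeq annotation of the human assembly GRCh38.p14, 4626 were updated through a synonym and 12245 matched nothing and kept the name given. That annotation served for names alone. The filter left 19802 named probes, and the brightest probe was kept for each of 15387 genes; 3587 of these genes had more than 1 probe past the filter.

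Per array, 13690 to 20459 named probes lay above background. The number of arrays limits the precision of every value.

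The 3 group means were fitted with limma on all 9 arrays, with moderated two-sided tests and Benjamini-Hochberg adjustment over all genes, and a gene was called at an adjusted p under 0.05. The 4 contrasts were MRX34 against the equally weighted mean of both controls, against empty liposomes and against dilution buffer, and empty liposomes against dilution buffer. Of 35 gene lists, the 34 with at least 3 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. A list's value is the median log2 fold change of its tested members. The difference between array means of a list was also put to an exact permutation test over the 84 choices of 3 arrays.

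The genes named in the text followed a rule. In each contrast with fewer than 5 genes past the threshold in a direction, the 5 with the smallest p in that direction are named, placeholders passed over. From each list described, up to 2 members with the smallest p are named where none passed. A fixed set of miR-34a targets and the tumour markers AFP and GPC3 are always given. Any gene outside the rule is said to be so.

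The tests, lists, naming rule and most alternatives were fixed before the data were examined. The alternatives changed the background correction, normalization, source table, filter, probe rule, arrays in the fit, variance model, array weights, pairing, control group and set test, and left out each array in turn. Covariates for host-liver transcripts and for array brightness, fits without pairs of doubted arrays and a replicate block with 6 arrays were added after the data were seen. The host-liver level was the mean of GNMT and OTC, reduced to these genes after results with a longer set had been seen.

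Arrays of different groups share replicate numbers. Correlations of deviations from the group means, taken before any calls were compared, were 0.44, 0.49 and 0.28 for equal numbers of empty liposomes and MRX34, so that the numbers appeared to pair those groups. The labels do not state a pairing, so the unpaired fit was kept and the replicate block was run as an alternative.

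On data simulated for 15387 genes with 200 changed, the fit recovered 34.3% of changes of 1 log2 unit and 94.6% of changes of 2 in MRX34 against both controls. The shares were 17.9% and 88.1% against empty liposomes, and 17.6% and 89.8% against dilution buffer. Mean false calls in these 3 contrasts were 7.8, 6.2 and 6.4 genes. In empty liposomes against dilution buffer, where no change was simulated, a mean of 0.1 genes was called. The recovered shares apply to 100 changed genes at each size, and may be lower where fewer genes change. In the real data, limma did not call CLRN3 (2.45, adjusted p = 0.0972) or GBA3 (2.00, adjusted p = 0.237) in MRX34 against both controls. A lack of calls therefore does not exclude changes of 2 log2 units. A simulated list of 20 genes shifted by -0.5 was called in 10 of 10 simulations in each of the 3 MRX34 contrasts. The simulated noise was independent between genes. The simulation therefore does not show how camera fares on correlated lists, such as heat shock (estimated correlation 0.130) and hypoxia (0.452).

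Planned tests of miR-34a seed sites were not run, because no transcript sequences were used here. Blocking by chip was not run, because the files name no chip. Among the 1094 unnamed probes past the filter, limma called 0 in each contrast, and 39, 37, 43 and 83 had an unadjusted p under 0.05 in the order of contrasts above.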

Results

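Gene expression was measured on 9 arrays of RNA from Hep3B tumours in mouse liver, 3 after dilution buffer, 3 after empty liposomes and 3 after MRX34. Mean background-subtracted intensity per array was 425, 616 and 249 for dilution buffer, 163, 491 and 325 for empty liposomes, and 323, 512 and 496 for MRX34. Named probes above background ranged from 13690 (31.2%, empty liposomes 1) to 20459 (46.6%, dilution buffer 2). Between arrays of a group, the median absolute log2 difference of a gene was 0.218 to 0.487. Along the first principal component, which held 40.4% of the variance, empty liposomes 1 (85.6) and MRX34 2 (-45.6) lay farthest from the rest.

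The tumour markers were bright in every group. AFP, alpha-fetoprotein, averaged 15.3 ± 0.0955 log2 units in MRX34 (SD, n = 3) and 15.3 ± 0.104 in the 6 controls, close to the top of the intensity scale (47789), where quantile normalization leaves little room for a difference. GPC3, the oncofetal proteoglycan glypican-3, averaged 12.9 ± 0.394 in MRX34 and 12.9 ± 0.285 in the controls.

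Transcripts of 2 liver enzymes differed widely between arrays of the same group. GNMT (glycine N-methyltransferase) spanned 191-fold over the 9 arrays and OTC (ornithine transcarbamylase) 48.6-fold. Their mean level was 10.9 ± 3.13 log2 units in dilution buffer, 12.1 ± 1.39 in empty liposomes and 9.59 ± 1.68 in MRX34 (SD, n = 3 each). MRX34 minus controls was -1.89, with an exact two-sided permutation p of 0.214. Across the 9 arrays the level went with the log2 mean intensity at Pearson's r = -0.71 (permutation p = 0.0315) and Spearman's rho = -0.70 (permutation p = 0.0428). Without the 2 arrays farthest from the median, r was -0.67. The level was quantile normalized and the mean intensity was not, so a negative relation between them is partly built in. The 2 genes were singled out after their values and results with a longer set were seen, and the permutation p-values do not allow for that choice.

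**Figure D1:**
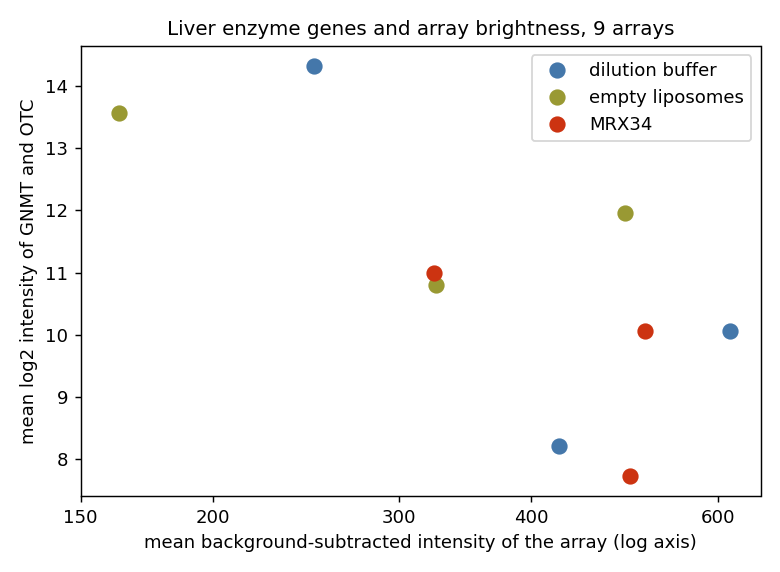
Mean log2 intensity of GNMT and OTC on each of the 9 arrays against its mean background-subtracted intensity, on a log axis, coloured by group. Dilution buffer 3 (14.3) and empty liposomes 1 (13.6) lie highest, on the dimmest arrays, and MRX34 3 (7.73) lies lowest.

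MRX34 against both controls asked which tumour transcripts differ 24 hours after the miR-34a mimic. THBS1, the secreted matrix protein thrombospondin 1, averaged 7.38 ± 0.0367 log2 units in MRX34 and 9.27 ± 0.412 in the 6 controls, a difference of -1.88 (SE 0.230). TENT5B (FAM46B in the table), of the poly(A) polymerase family, differed by -1.82 (SE 0.228), and the chaperones HSPH1 and DNAJB1 by -1.29 (SE 0.189) and -1.53 (SE 0.266). FOXK2, a forkhead transcription factor, differed by -1.06 (SE 0.172) and was above background on 1 of 3 MRX34 arrays. In the other direction, CLRN3, a clarin-family membrane protein, averaged 8.02 ± 0.299 in MRX34 and 5.57 ± 0.528 in the controls, a difference of 2.45 (SE 0.317), and lay above background on 3 of 6 control arrays. GBA3, the cytosolic beta-glucosidase, differed by 2.00 (SE 0.348), ASIP, agouti signalling protein, by 1.80 (SE 0.294), the alcohol dehydrogenase ADH4 by 1.67 (SE 0.288), and the long non-coding RNA EPB41L4A-AS1 (TIGA1 in the table) by 1.03 (SE 0.181). For each of these 10 genes, all 3 MRX34 arrays lay beyond all 6 controls. They were named for the smallest p in this contrast, so the separation follows in part from that choice. ASIP was above background on 4 controls and the genes other than ASIP and CLRN3 on all 6.

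With limma, 0 of 15387 genes passed an adjusted p under 0.05, and 1710 had an unadjusted p under 0.05 (1057 higher and 653 lower in MRX34). Chance alone would give 769 on average, but genes on an array vary together, so such counts spread widely. At least 1710 were reached by 10 of 100 splits of the arrays, the real one among them (highest other 2783). The smallest adjusted p was 0.0972, shared by THBS1, TENT5B and CLRN3, followed by 0.182 for HSPH1 and 0.237 for the others named. THBS1 was called without background correction, with normexp at an offset of 50 that did not use the detection p-values, with the strict filter, with a trended and robust variance and without dilution buffer 1. Array weights called 1464 genes, THBS1 among them. Those weights were 8.13 for dilution buffer 2 and 4.65 for MRX34 3, and at most 0.904 for the other arrays of these 2 groups. In 19 of 25 alternatives 0 genes were called.

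**Figure D2:**
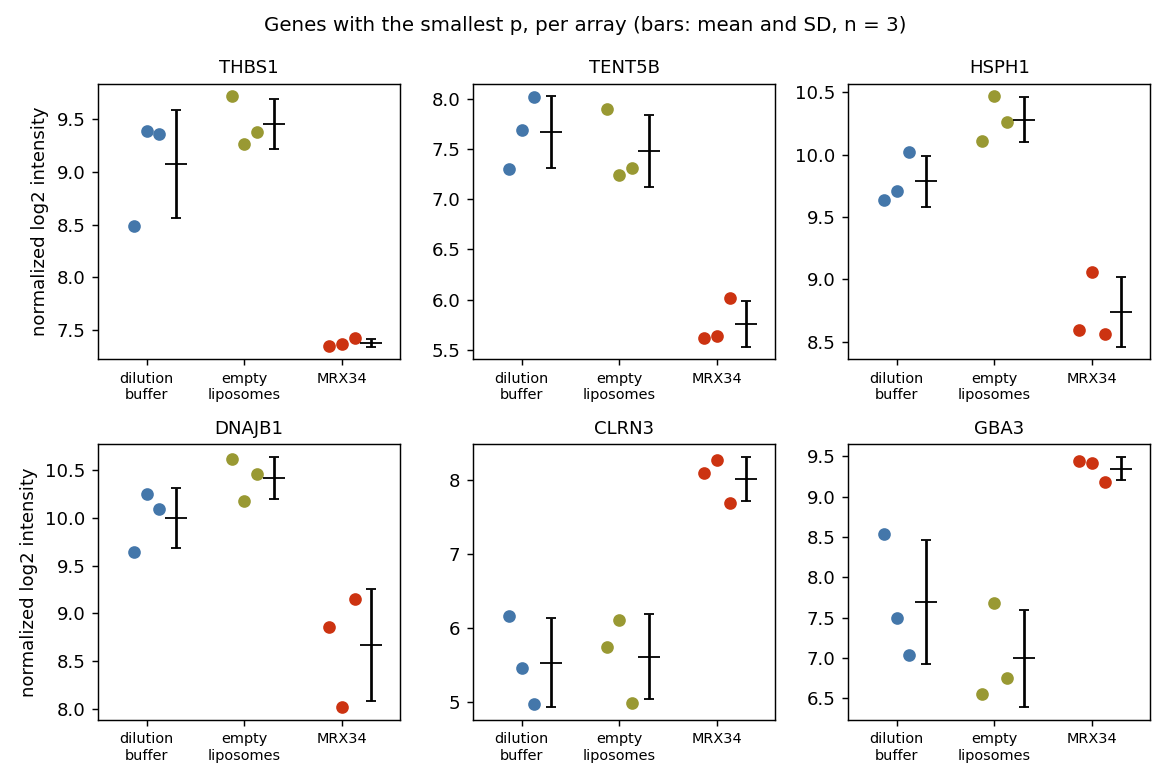
Normalized log2 intensity of THBS1, TENT5B, HSPH1, DNAJB1, CLRN3 and GBA3 on each array, with bars for the mean and SD of each group (n = 3). In all 6 panels the 3 MRX34 arrays lie beyond the 6 controls, below them for the genes at -1.29 to -1.88 and above them for CLRN3 and GBA3. The genes were chosen for a small p in MRX34 against both controls.

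Heat shock genes, the chaperones and co-chaperones induced by protein stress, lay lower in MRX34 than in both controls. Of the 18 members, 16 were lower and the median log2 fold change was -0.54, with 7 members passing when adjusted over the list alone and 0 over all genes. These were HSPH1, DNAJB1, HSPA1B (-1.02), BAG3 (-1.04), CHORDC1 (-0.87), HSPA1A (-0.98) and the collagen chaperone SERPINH1 (-0.75). HSPA1A and HSPA1B are near-identical copies of stress-inducible HSP70. The list means per array were -0.47, -0.32 and -0.38 in MRX34, -0.17, 0.09 and 0.40 in dilution buffer, and 0.27, 0.31 and 0.27 in empty liposomes. The constitutive HSP90AA1 (0.02) and the mitochondrial HSPE1 (0.45) were the 2 members not lower. Camera gave the list an adjusted p of 1.2e-08, and adjusted p = 0.309 with an estimated correlation; fry gave an adjusted p of 0.0461. The exact permutation test gave p = 0.0119 (1 of 84 choices of arrays), adjusted p = 0.135, and gave the same values for the epithelial list and for lymphocyte and granulocyte markers. The 2-gene liver level was also lowest on average in MRX34 (9.59), and dilution buffer 3, highest of all for heat shock genes, held the highest liver level (14.3).

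Hypoxia genes, targets of the HIF transcription factors, lay higher in MRX34, with 25 of 28 members higher and a median of 0.49. Examples were the mitophagy receptor BNIP3L (1.04, SE 0.271) and the collagen prolyl hydroxylase P4HA1 (0.86, SE 0.281). Of the 28, 10 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone. Camera gave an adjusted p of 1.24e-04, and adjusted p = 0.692 with an estimated correlation; fry gave 0.349, and the exact permutation test p = 0.107 (adjusted p = 0.434). The hypoxia means were lowest on empty liposomes 1 (-0.73) and dilution buffer 3 (-0.70), the arrays with the highest 2-gene liver levels (13.6 and 14.3), and with that level as a covariate the median was 0.31, adjusted p = 0.0420.

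**Figure D3:**
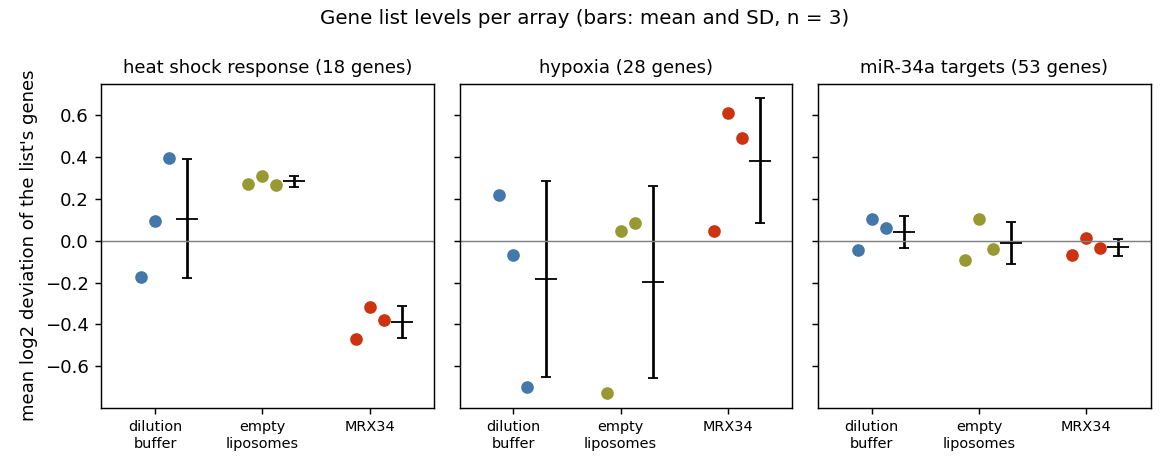
Mean log2 deviation per array of the heat shock (18 genes), hypoxia (28) and miR-34a target (53) lists, by group. Heat shock means lie at -0.47 to -0.32 in MRX34 and at -0.17 to 0.40 in the controls, while the hypoxia and target means of the groups overlap.

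The miR-34a target list, 53 of 69 genes tested, had a median of -0.03 in MRX34 against both controls, with 23 members higher and 30 lower. MYC, the transcription factor, differed by -0.51 (SE 0.168), CCND1, cyclin D1, by -0.33, NOTCH1 by -0.35 and CTNNB1, beta-catenin, by -0.86 with an SE of 0.507; the 3 CTNNB1 probes past the filter gave -0.86, -1.06 and 0.43. LDHA, lactate dehydrogenase A, differed by 0.46 (its probes by 0.46, 0.27 and 0.97), CCNE2 by 0.50 and FOXP1 by 0.44. CDK4 (0.19), CDK6 (0.15), HDAC1 (0.12), SIRT1 (0.04), E2F3 (-0.11) and AXL (0.24, above background on 3 of 9 arrays) lay closer to 0, and MET averaged 9.33 in both. The members with the smallest p were MYCN (-1.10, SE 0.288), a relative of MYC, and PPP1R10 (-0.65, SE 0.183), a phosphatase regulator. BCL2, CD44 and CD274 were not tested, their best probes lying above background on 2, 0 and 0 arrays. No member passed when adjusted over the list alone (0 of 53), 6 had an unadjusted p under 0.05 (2 higher, 4 lower), and camera gave the list an adjusted p of 0.360, or adjusted p = 0.692 with an estimated correlation.

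**Figure D4:**
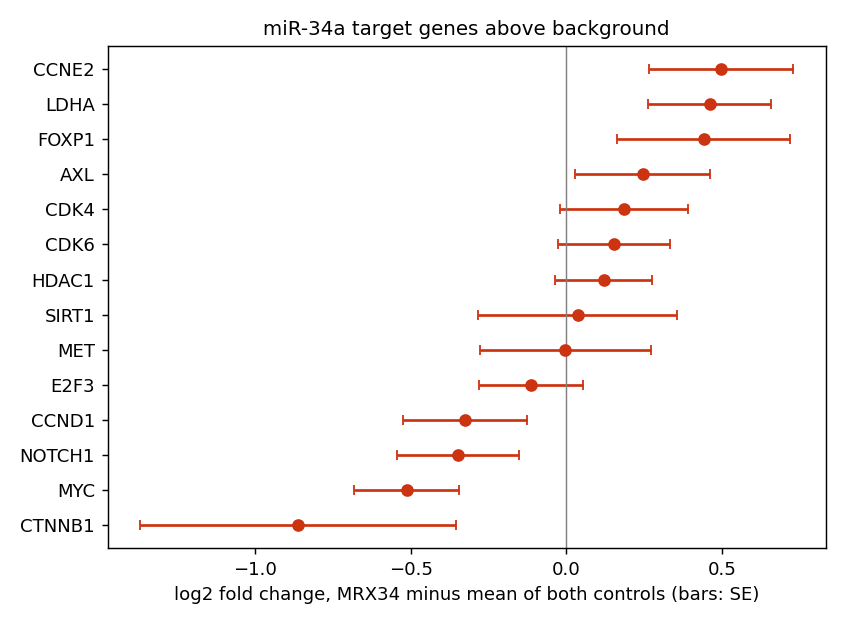
Log2 fold change of 14 miR-34a target genes in MRX34 minus the mean of both controls, with bars for the SE of the limma fit (9 arrays). Values run from -0.86 for CTNNB1 to 0.50 for CCNE2, and none passed the adjusted threshold.

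Beyond heat shock and hypoxia, 32 lists were not called in MRX34 against both controls, and the values of most of them follow. The Notch (-0.21), NF-kB and inflammatory (-0.25) and PPARA and fatty acid oxidation (0.25) lists each had an adjusted p of 0.0931, and the epithelial (-0.16) and immediate early gene (-0.18) lists 0.149. NF-kB genes were called with the replicate block (adjusted p = 0.0236), and without empty liposomes 1 the number of lists called was 4, with Notch and NF-kB genes added. Each of these had adjusted p = 0.626 with an estimated correlation. Medians were 0.27 for lymphocyte and granulocyte markers, 0.30 for LXR targets, 0.16 for adult hepatocyte metabolism, 0.13 for apoptosis regulators, -0.14 for the unfolded protein response, -0.10 for antigen presentation, 0.10 for oxidative phosphorylation and 0.09 for fatty acid synthesis and storage. DNA replication and S phase (0.04), NRF2 and metallothioneins (-0.01), and oncofetal liver tumour genes (-0.00) had medians near 0, as had the 5 fibroblast and stellate cell markers (-0.02), whose mean was -0.32. The median, the mean and camera's direction did not share 1 sign in these lists: G2 and mitosis (0.08), Wnt targets (0.01), interferon-stimulated genes (0.01), acute phase proteins (0.06), hepatocyte plasma proteins (0.02), cholesterol synthesis (-0.01), lysosome and autophagy (0.00), miRNA machinery (0.01), ATF4 and amino acid response (0.04, mean -0.05), mesenchymal genes (0.23), macrophage and Kupffer cell markers (-0.02), erythrocyte genes (0.05) and ribosomal proteins (0.05). The endothelial list had 1 member above background, PECAM1 (0.73), and was not tested.

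MRX34 against empty liposomes set the mimic against its carrier. THBS1 again showed the smallest p, at -2.07 (SE 0.266), with HSPH1 at -1.54 (SE 0.219), HSPA1B at -1.34 (SE 0.211), DNAJB1 at -1.75 (SE 0.307) and TENT5B at -1.73 (SE 0.263). Higher in MRX34 were CLRN3 (2.40, SE 0.366), GBA3 (2.35, SE 0.402), FAM162B (1.68, SE 0.278), the U3 small nucleolar RNA SNORD3C (1.67, SE 0.275) and EPB41L4A-AS1 (1.27, SE 0.209). CLRN3 and SNORD3C were above background on 1 of 3 liposome arrays each and FAM162B on 2. Heat shock genes had a median of -0.73, with 13 of 18 lower and 8 passing when adjusted over the list alone, all lower. Hypoxia genes had a median of 0.56, with 23 of 28 higher and 0 passing when adjusted over the list alone; BNIP3L differed by 1.13 (SE 0.313) and the glycolytic regulator PFKFB4 by 1.23 (SE 0.390).

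With limma, 0 of 15387 genes passed an adjusted p under 0.05 in this contrast, and 1439 had an unadjusted p under 0.05 (968 higher, 471 lower); the genes named under the rule for smallest p had an adjusted p of 0.235. Camera called heat shock (adjusted p = 1.3e-09; adjusted p = 0.244 with an estimated correlation; fry 0.0621) and hypoxia (adjusted p = 0.0018; adjusted p = 0.794 with an estimated correlation; fry 0.641). It also called immediate early genes (median -0.38, mean -0.18, 13 of 20 lower, adjusted p = 0.0256; adjusted p = 0.601 with an estimated correlation; fry 0.172), with JUN at -0.61 (SE 0.214) and FOS at 1.61 (SE 0.575). Without empty liposomes 1, Notch and NF-kB genes were called as well; on all 9 arrays they had adjusted p = 0.690 and adjusted p = 0.794 with an estimated correlation. The target list had a median of -0.06 and an adjusted p of 0.412. The 2-gene liver level was 9.59 in MRX34 and 12.1 in empty liposomes, with array brightness as a covariate the hypoxia median was 0.26 (adjusted p = 0.0200), and with the liver level the hypoxia median was 0.18 (adjusted p = 0.378) and the immediate early median -0.26 (adjusted p = 0.0989). Hypoxia was not called without empty liposomes 2 (0.62) or MRX34 2 (0.30), and its median was 0.33 without empty liposomes 1; in the replicate block with 6 arrays, 0 genes passed, heat shock (-0.73, adjusted p = 1.16e-07) and hypoxia (0.65, adjusted p = 4.91e-05) were called, and the immediate early list was at -0.37 (adjusted p = 0.155).

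MRX34 against dilution buffer set the mimic against the article without carrier. TENT5B differed by -1.91 (SE 0.263), THBS1 by -1.70 (SE 0.266), the oestrogen-responsive GREB1 by -1.80 (SE 0.295), the poly(A)-binding protein gene PABPC3 by -1.49 (SE 0.252) and FOXK2 by -1.09 (SE 0.198). Higher were CLRN3 (2.49, SE 0.366), ADH4 (1.71, SE 0.332), OGA (MGEA5 in the table), which removes O-GlcNAc from proteins (1.21, SE 0.234), DENND2C (1.03, SE 0.197) and the ribosomal pseudogene RPS26P10 (1.31, SE 0.243). Heat shock genes had a median of -0.54, with 17 of 18 lower and 8 passing when adjusted over the list alone, 7 of them lower and HSPE1 higher (0.82). Hypoxia genes had a median of 0.52, with 25 of 28 higher and 0 passing when adjusted over the list alone; BNIP3L was at 0.95 (SE 0.313) and P4HA1 at 0.95 (SE 0.325). MYC differed by -0.66 (SE 0.194) and MYCN by -1.51 (SE 0.332).

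With limma, 0 of 15387 genes passed an adjusted p under 0.05 in this contrast, and 1561 had an unadjusted p under 0.05 (898 higher, 663 lower); the genes named under the rule for smallest p had an adjusted p of 0.399. Camera called heat shock (adjusted p = 2.41e-05; adjusted p = 0.734 with an estimated correlation; fry 0.0836) and hypoxia (adjusted p = 3.15e-04; adjusted p = 0.734 with an estimated correlation; fry 0.442). NF-kB genes (median -0.31) were called with the replicate block (adjusted p = 0.0241) and without dilution buffer 1, and PPARA genes without empty liposomes 1. Each of these had adjusted p = 0.734 with an estimated correlation. The target list had a median of -0.04 and an adjusted p of 0.400. The 2-gene liver level was 9.59 in MRX34 and 10.9 in dilution buffer. With that level as a covariate the heat shock median was -0.26 (adjusted p = 0.00118). Without dilution buffer 3, the array with the highest liver level, the heat shock median was -0.22 (adjusted p = 0.00594) and the hypoxia median 0.33 (adjusted p = 0.0952, not called). The same 3 MRX34 arrays enter all 3 contrasts, which are therefore not independent.

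Empty liposomes against dilution buffer compared the carrier with the buffer. DGAT2, the last enzyme of triglyceride synthesis, differed by 1.66 (SE 0.285), the serine protease PRSS8 by 1.70 (SE 0.301), the plasma protein FETUB by 1.36 (SE 0.229), the corepressor CTBP2 by 1.44 (SE 0.302) and FIGNL2 by 1.00 (SE 0.203). Lower in liposomes were the formin FMNL2 (-1.62, SE 0.331), the lysosomal membrane protein TMEM192 (-1.34, SE 0.221), ANAPC15 (C11orf51 in the table), of the anaphase-promoting complex (-1.07, SE 0.241), TSNAX (-0.98, SE 0.225) and the growth factor BMP7 (-0.97, SE 0.198). Interferon-stimulated genes had a median of 0.27, 20 of 28 higher, with IFI6 at 0.78 (SE 0.274) and IRF9 at 0.62 (SE 0.230). Heat shock genes had a median of 0.34, 12 of 18 higher, with HSPE1 at 0.75 (SE 0.230) and HSPA1B at 0.65 (SE 0.211). PRSS8 and FIGNL2 were above background on 1 buffer array each, CTBP2 on 2, TMEM192 on 1 liposome array, and FMNL2 and ANAPC15 on 2.

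With limma, 0 of 15387 genes passed an adjusted p under 0.05 in this contrast, and 888 had an unadjusted p under 0.05 (422 higher, 466 lower), against 769 on average by chance. The genes named under the rule for smallest p had an adjusted p of 0.765. Camera called 0 of 34 lists, but 6 without empty liposomes 1, 2 without dilution buffer 3, 1 without dilution buffer 2, and 7 without dilution buffer 3 and empty liposomes 1. Interferon-stimulated and heat shock genes had the smallest adjusted p, 0.0853 each, and adjusted p = 0.942 with an estimated correlation; 0 members of either passed when adjusted over the list alone, and 6 and 4 had an unadjusted p under 0.05. The target list had a median of -0.00 and an adjusted p of 0.942. The 2-gene liver level was 12.1 in empty liposomes and 10.9 in dilution buffer.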

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

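Covariates for the 2-gene liver level and for array brightness, the fits without 2 doubted arrays and the replicate block with 6 arrays were chosen only after the data were seen. The miR-34a target list was not called in any of its 27, 28, 27 and 27 alternatives in the 4 comparisons (medians -0.13 to -0.02 against both controls). None of the named genes was called with the main settings. Over the alternatives, 3135 of their values stayed uncalled and 65 newly passed, 0 of these with a reversed direction. Array weights gave most of the new passes: 18 against both controls, 10 against empty liposomes, 21 against buffer and 4 in liposomes against buffer. Direction was not compared for values called in neither fit. For each result that changed, the cause was not tested.

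Against both controls, 0 genes became 2 without background correction and 2 with normexp at offset 50 without detection p-values (CLRN3 and THBS1 both times), 3 with the strict filter (THBS1, HSPH1 and LOC728411), 1 with a trended, robust variance (THBS1) and 1464 with array weights of 0.262 to 8.13. Against empty liposomes they became 3 with that variance (THBS1, HSPH1 and HSPA1B) and 267 with array weights. Array weights called 2827 against buffer and 6 in liposomes against buffer. Leaving out 1 array gave 0 to 1 genes against both controls (THBS1 without dilution buffer 1), 0 to 4 against empty liposomes (4 without empty liposomes 2) and 0 elsewhere. Counts at an unadjusted p under 0.05 moved by over 1.5 times against both controls without MRX34 2 (1052), against empty liposomes without empty liposomes 1 (946) or 2 (2583), against buffer without dilution buffer 2 (780) or 3 (830), and in liposomes against buffer without dilution buffer 2 (427) or empty liposomes 1 (542) or 2 (2006). Median scaling moved the median of all genes to -0.17 against empty liposomes and 0.14 in liposomes against buffer.

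With an estimated correlation no list was called: heat shock -0.54, -0.73 and -0.54, hypoxia 0.49, 0.56 and 0.52, and immediate early genes -0.38. With fry, of these, heat shock against both controls alone was called. Hypoxia was also lost with the strict filter (0.26 against liposomes, 0.43 against buffer), and against liposomes with the liver covariate (0.18) and without MRX34 2 and empty liposomes 1 (0.18). Leaving out 1 array gave hypoxia 0.30 to 0.77 against liposomes, 0.33 without empty liposomes 1, not called without empty liposomes 2 (0.62) or MRX34 2 (0.30), and 0.33 to 0.71 against buffer, not called without dilution buffer 3 (0.33). Heat shock stayed called in every such fit, at -0.67 to -0.44, -0.78 to -0.59 and -0.71 to -0.22, the last without dilution buffer 3. Immediate early genes against liposomes lost their call with median scaling (-0.44), the strict filter (-0.44), the mean of probes (-0.33), the compared groups alone (-0.37), array weights (-0.19), the liver (-0.26) and brightness (-0.29) covariates, without dilution buffer 3 and empty liposomes 1 (-0.30), without MRX34 2 and empty liposomes 1 (-0.11) and in the replicate block with 6 arrays (-0.37), where hypoxia stayed called (0.65). Leaving out 1 array gave them -0.42 to -0.21, not called without dilution buffer 2 (-0.37), empty liposomes 1 (-0.30) or 2 (-0.35), or MRX34 1 (-0.32) or 2 (-0.21).

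Lists gained calls too: in liposomes against buffer interferon-stimulated genes in 11 of 27 alternatives and heat shock in 6. With the replicate block on 9 arrays, 0 genes passed in each comparison, heat shock, hypoxia and immediate early calls stood, and NF-kB genes were called against both controls (-0.25, adjusted p = 0.0236) and buffer (-0.31, adjusted p = 0.0241). Equal replicate numbers correlated at -0.19, 0.30 and -0.32 between buffer and liposomes, and at -0.06, 0.14 and -0.15 between buffer and MRX34, so numbers did not pair those groups. Seed-site, 8mer and chip alternatives were not run. Signal over background limits BCL2, CD44 and CD274, which were not tested.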

Other observations

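The adult hepatocyte list was not called in MRX34 against both controls (13 members higher and 10 lower, median 0.16, mean 0.02, adjusted p = 0.380, and adjusted p = 0.856 with an estimated correlation; exact permutation p = 0.905). Its members ADH4 (1.67, SE 0.288), the glucuronosyltransferase UGT2B7 (0.66, SE 0.173) and the glucose-6-phosphatase G6PC1 (0.97), the last named after its value was seen, passed when adjusted over the list alone, 3 of 23. The lipid-droplet protein CIDEC differed by 1.87 (SE 0.452) and passed when adjusted over its list of 23 alone, while the lipase PNPLA3, above background on 1 of 3 MRX34 arrays, was at -0.54 (SE 0.207). The zinc exporter SLC30A1 (0.85, SE 0.180) passed over the NRF2 and metallothionein list alone. IGF2, the fetal growth factor, was at -1.46 (SE 0.394) and the biliary keratin KRT19 at -0.86 (SE 0.246). The lists of these genes were not called, and all of the genes had an adjusted p over all genes above 0.05 in limma, from 0.237 for ADH4 upward.

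CD3D, a part of the T-cell receptor complex, differed by 0.97 (SE 0.214) and S100A9, a myeloid calcium-binding protein, by 1.25 (SE 0.321), the 2 of 6 tested lymphocyte and granulocyte markers that passed over their list alone; the list was not called (adjusted p = 0.199). CD3D was above background on 1 of 6 controls and S100A9 on 3. The chemokine CXCL10 was at 0.67 (SE 0.177) and IFI6 at -0.75 (SE 0.237). Complement C3 was at -1.92 (SE 0.550) and above background on 2 of 3 MRX34 arrays. RPLP0, singled out after its values were seen, read 8.98 on MRX34 2 and 13.13 to 13.65 on the other arrays. It was not alone among the genes with the widest range. GET4 read 5.90 on MRX34 2 and 9.81 to 10.78 elsewhere, and PRRC2A 5.74 and 9.14 to 10.53. All MRX34 contrasts include this array, and the cause was not tested.

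The tests with the host-liver covariate, the counts of other splits for the 2 gene lists and by numbered pairs, the replicate block with 6 arrays, and all 3 tests for the 2 liver enzymes were chosen only after the result was seen, and the brightness covariate after the array intensities were seen.

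Heat shock genes were lower in MRX34 than in both controls (median -0.54). With the liver covariate the median was -0.41 (camera at the preset correlation, adjusted p = 5.42e-06), and with the brightness covariate -0.51 (adjusted p = 1.07e-07). The medians argue against host liver RNA or array brightness as the whole cause in that comparison. The p-values depend on the preset correlation. In the comparison with dilution buffer alone, however, the liver covariate took the median from -0.54 to -0.26 (camera, adjusted p = 0.00118). Leaving out each of the 9 arrays gave medians no higher than -0.44 against both controls, which argues against 1 array alone in that comparison. Against dilution buffer, the median was -0.22 without dilution buffer 3, the array with the highest liver level. Only 1 of 84 splits of the arrays, the real one, gave a difference as large (0.584, highest other 0.512), the smallest p that 84 splits allow. This list was picked from 34, and 2 others reached the same p (exact permutation test, adjusted p = 0.135). So few splits pass the adjustment only where many lists reach it, so chance was left open. These splits ignore the replicate numbers. Within the numbered pairs of empty liposomes and MRX34 the heat shock differences were -0.74, -0.63 and -0.65. An effect of the mimic on stress chaperones stays open as an untested hypothesis. So do chance and handling of the animals, which was not tested; with an estimated correlation the median was the same and the list was not called (adjusted p = 0.309, in a range of 6.0e-10 to 0.309 over the alternatives).

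Hypoxia genes were higher in MRX34 than in both controls (median 0.49). With array brightness as a covariate the median was 0.37 (camera at the preset correlation, adjusted p = 2.30e-04). Against empty liposomes alone that covariate took the median from 0.56 to 0.26 (camera, adjusted p = 0.0200). The list's estimated correlation was 0.452, and with it camera did not call the list even without a covariate (adjusted p = 0.692). These p-values therefore do not decide on array brightness. Host liver RNA cannot be told apart from the treatment here, because the liver covariate took the median to 0.31 with an adjusted p of 0.0420, close to the threshold, in a range of 3.93e-07 to 0.692 over the alternatives. In 9 of 84 splits the difference was as large (0.574, highest other 0.749), so chance could not be excluded by these splits, which ignore the replicate numbers. Within the numbered pairs of empty liposomes and MRX34 the hypoxia differences were 0.77, 0.56 and 0.41, and the replicate block with 6 arrays gave a median of 0.65 (adjusted p = 4.91e-05, in a range of 9.92e-07 to 0.794 over the alternatives of that comparison).

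GNMT and OTC differed between arrays of 1 group. On the 2 dimmest arrays the 2 genes already lay above their median on the other 7 before scaling; the smaller of the 2 log2 ratios was 1.91 at the median of the 2 genes, which argues against array brightness and normalization. Were hepatocyte genes of the tumour cells turned on together, the 20 other adult hepatocyte genes would follow the 2, but the upper quartile of their slopes was -0.0360 and 15 of 20 slopes lay below 0. Host liver RNA in the tumour sample may account for the pattern, as mouse RNA that binds few human probes would leave arrays dim. The level was higher on dimmer arrays (rho = -0.70). However, quantile normalization raises a given signal on a dim array, so a negative rho is partly built in and does not decide for this cause. Hep3B is itself a liver line and the 2 genes were picked from these arrays, so this remains a hypothesis.

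Other splits of the 9 arrays into groups of the same sizes were counted for the gene counts. With 0 genes called by limma, every split reaches the count, so the 100 of 100 splits against both controls (highest other 5) and the 10 of 10 against empty liposomes (highest other 3), against dilution buffer (highest other 0) and in empty liposomes against dilution buffer (highest other 0) decide nothing. Against both controls, 10 of 100 gave as many at an unadjusted p under 0.05 (1710, highest other 2783), so chance could not be excluded by these splits. They ignore the apparent pairing of empty liposomes and MRX34. That pairing was read from correlations of these same arrays and is not stated by the labels. Of the 9 arrays, 6 correlated best with an array of their own number. The largest count put dilution buffer 3, empty liposomes 1 and empty liposomes 3 together, a structure of the samples other than the groups. Among the 11 of these splits that part all numbered pairs, too few for a share under 0.05, the real count was matched by 1, the real split (highest other 1544), and among the other 89, which do not part them all, by 9. The 10 splits of 6 arrays are too few for a share under 0.05. Against empty liposomes, 2 of 10 gave at least 1439 at an unadjusted p under 0.05 (highest other 3219, with empty liposomes 1, empty liposomes 3 and MRX34 1 together). Among the 4 splits that part all numbered pairs the highest other was 321, and among the remaining 6, which keep pairs together, 3219. Counts by numbered pairs decide nothing, because splits that part correlated arrays tend to give small counts and splits that keep them together large ones. Against dilution buffer, 1 of 10 gave at least 1561 (highest other 675). In empty liposomes against dilution buffer, 4 of 10 gave at least 888 (highest other 1635).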
